A study of Mus musculus with 6 samples.

How the data were processed

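RNA from microdissected midbrain and striatum of adult wild-type C57BL/6 mice was profiled by methylated RNA immunoprecipitation sequencing (MeRIP-seq). In this assay an antibody against N6-methyladenosine (m6A), a methyl mark on adenosines inside RNA, pulls down RNA fragments that carry the mark. Input RNA that did not go through the pull-down serves as the background. Per the labels' protocols, total RNA was depleted of ribosomal RNA with RiboMinus and the immunoprecipitation was done in 2 rounds. There were 6 libraries, 3 MeRIP and 3 input, with the same replicate numbers in both groups. The labels give both brain areas together as 1 tissue for every library, so midbrain and striatum cannot be compared.

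The data used here are 1 deposited list of peak positions that the labels attach to all 6 libraries. Per the submitters' processing notes, BWA 0.6.2-r126 and SAMtools 0.1.18 were used and the genome build was mm9. The roles of these tools, the peak caller, its threshold, and how the 3 MeRIP and 3 input libraries were combined are not given in the sources used here. The authors' list has 3 columns, the chromosome, start and end of each peak. No height, fold enrichment, p-value, strand, gene name or value per library came with it. The sequencing depth of each library is therefore unknown here. No statement below has a replicate error between animals or libraries, and intervals and p-values describe the spread along the genome within this 1 list.

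Testing the positions showed that touching peaks formed contiguous runs. In 100% of the runs both ends lay on a grid of 25 bases, and in 100% the number of peaks equalled the fewest pieces of at most 200 bases that the run could be cut into. Peak width thus depends on this cutting. Touching peaks were joined, and the joined interval is called an enriched region. Files in this format count positions from 0; coordinates are printed counting from 1, in mm9.

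Density was the number of regions divided by the distance from the first to the last peak of a chromosome. Its 95% interval came from 1000 bootstrap draws of blocks of 5 Mb. Each of 20 chromosomes was compared with the others by permuting complete blocks 10000 times (two-sided, Benjamini-Hochberg over 20 tests). Spacing was the distance to the nearest other region. It was set beside 1000 placements of regions of the same widths at random positions between the first and last peak of the same sequence. Such placements also fall on untranscribed sequence, where RNA gives no peaks, so a larger share of close neighbours in the list is given in advance; they serve as a scale and not as a test. Regions up to 10 kb apart were linked into loci; a locus is a unit of distance only and can hold part of a gene or several genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Joining, the spacing measure, the test of locus edges and the comparison of widths were tested on simulated data. The block permutation and block bootstrap of density were not. Of 5000 simulated regions, 100% were recovered after cutting and joining. Their pieces touched and the regions were kept apart, so this was given by construction. It checks only that the joining step ran correctly. The test of locus edges called 85% of 20 simulated sets in which the widest region was moved to an edge in 5% of loci, a mean excess of 2.46 percentage points. It called 100% of 20 sets with 10% of loci moved, a mean excess of 4.61 points, and 6% of 50 sets with no effect. The comparison of widths called 81% of 100 simulated sets with isolated regions made 10 bases narrower, 99% of 100 sets with 15 bases, and 6% of 100 sets with no shift. These sets had widths shuffled over all regions and were tested by permuting within chromosomes. The rates therefore hold only for widths that are independent between regions.

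No genome or annotation of mm9 was used here. The gene table at hand belongs to another build, GRCm38, and was used only for gene names and for which genes neighbour each other. Peaks were therefore not placed on genes, exons, untranslated regions or stop codons. The planned comparisons by transcript region, distance to the stop codon, sequence motif, gene list and peaks per gene were not made. The rule for named items, fixed before the data were examined, then called for the 5 widest peaks and the 3 chromosomes of highest and lowest density. Because 4147 peaks shared the maximum width, the widest enriched regions are named instead. The loci, bins and mitochondrial regions were chosen for description after the positions were seen.

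Alternatives fixed before the data were examined were peaks at or above the median width, peaks within 100 bases joined, and autosomes and X only. The others were added afterwards.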

Results

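Transcriptome-wide m6A was mapped in midbrain and striatum tissue of adult wild-type mice, the brain areas that hold the dopamine-producing neurons and one of their main target fields. The map rests on 3 MeRIP and 3 input libraries. It addresses where in the genome RNA marked with m6A was detected; how the input libraries entered the peak calls is not given in the sources used here. The authors' list held 42886 peaks and gave positions without values per library, so the spread between replicates and the depth could not be given for any peak.

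Enrichment was found on 20 assembled chromosomes (every autosome and X), on the mitochondrial sequence, and on 5 sequences labelled random, with 0 peaks listed on Y. Each sequence labelled random is named for a chromosome. Peaks had a median width of 159 bases, with an interquartile range of 125 to 175 bases and limits of 100 and 200 bases. Of all peaks, 31280 (72.9%) touched another peak end to end, and 0 pairs overlapped. After touching peaks were joined, 23446 enriched regions remained, which covered 6.68 Mb. Their median width was 225 bases, with an interquartile range of 150 to 350 bases and a mean of 285 ± 218 bases (SD over regions).

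Enriched regions ranged from short stretches near the minimum width to a small class of long ones. Regions of 200 bases or less numbered 11606 (49.5%). The 2705 regions over 500 bases made up 11.5% of regions and 30.8% of covered bases. The 340 regions over 1000 bases made up 1.45% of regions and 6.71% of covered bases, and 16 regions were longer than 2000 bases.

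The widest region in the list was mitochondrial and ran from base 11601 to base 14275, a width of 2675 bases that the list held as 14 peaks. The widest nuclear regions were both 2525 bases wide. One lay on chromosome 1 from 33857801 to 33860325, and the other on chromosome 11 from 117582301 to 117584825. Next came a region of 2375 bases on chromosome 11, from 49028551 to 49030925, and a region of 2350 bases on chromosome 19, from 59373851 to 59376200. The genes at these positions were not determined here.

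**Figure D1:**
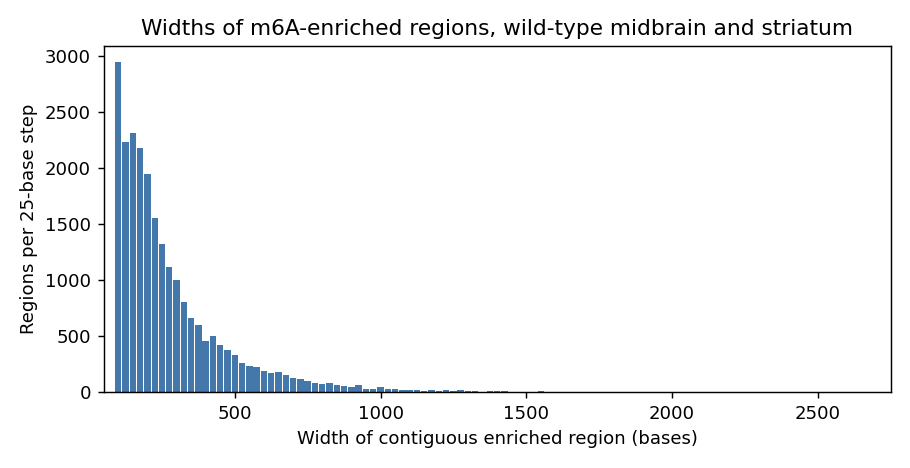
Widths of the 23446 contiguous enriched regions (x axis, bases) against the number of regions per 25-base step (y axis, linear). The bars are highest at the minimum width of 100 bases, with 2941 regions, and the tail reaches 2675 bases.

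The density of enriched regions differed between chromosomes, with chromosome 11 at the top and chromosome X at the bottom. Chromosome 11 carried 1717 regions, or 14.5 per Mb (95% block bootstrap interval 10.7 to 18.3), which was 1.63 times the density of the other chromosomes together. Chromosome X carried 733 regions, or 4.56 per Mb (3.25 to 6.01), which was 0.482 times the density of the autosomes. Both differences passed the two-sided block permutation test, with an adjusted p of 0.009 for each. The other 18 chromosomes did not pass it. The test and the intervals treat blocks of 5 Mb as independent. Neighbouring blocks of a chromosome may not be, so the p-values can be too small and the intervals too narrow.

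Among those 18, chromosome 19 had 12.3 regions per Mb (7.01 to 18.4) and chromosome 17 had 11.3 per Mb (7.27 to 16.0). At the lower end, chromosome 14 had 7.44 regions per Mb (5.61 to 9.31) and chromosome 1 had 7.49 per Mb (6.01 to 9.05). The median over the 20 chromosomes was 9.01 regions per Mb. Region width varied less than density, with a median of 200 bases on chromosome 11 and on chromosome X, and 225 bases on chromosome 1 and on chromosome 19. The list holds only enriched positions, so gene number, expression and enrichment are not separated in these densities.

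**Figure D2:**
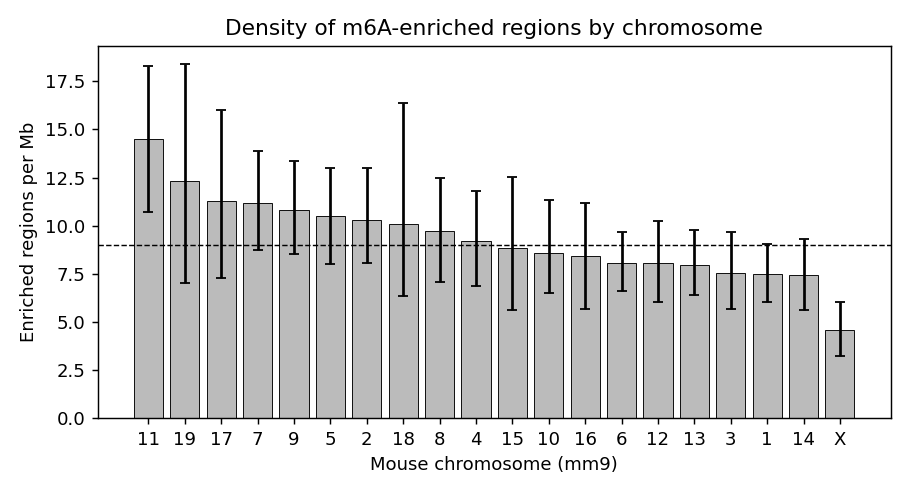
Enriched regions per Mb (y axis, from 0) for each autosome and X (x axis, ordered by density), with 95% block bootstrap intervals as error bars and the median of 9.01 as a dashed line. Chromosome 11 stands at 14.5 and chromosome X at 4.56 regions per Mb.

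The spacing of enriched regions varied widely. The median distance to the nearest other region was 900 bases, and 12043 of 23446 regions (51.4%, exact binomial interval 50.7 to 52.0) had another region within 1 kb. Of all regions, 4584 (19.6%) lay within 100 bases of another. After regions within 100 bases were joined, the share with another within 1 kb was 40.4%. Random placement put a mean of 2.50% of regions within 1 kb of another. When each region was placed only within its own 1-Mb bin, which keeps the regional density, the mean share was 5.0% against 51.3% in the list on autosomes and X. These placements also fall on untranscribed sequence, where no peak can arise, so an excess over them was given in advance and is no test of grouping within transcripts. Regions are not independent of one another, so the binomial interval covers counting error only.

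At the other end of the range, 6173 regions (26.3%) had no other region within 10 kb, and 1284 (5.48%) had none within 100 kb. Linking regions up to 10 kb apart gave 11697 loci. Of these, 6173 (52.8%) held 1 region, 2667 (22.8%) held 2 and 2857 (24.4%) held 3 or more. The loci of 3 or more regions held 50.9% of all regions and had a median span of 4.55 kb. There were 52 loci with 10 or more regions.

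**Figure D3:**
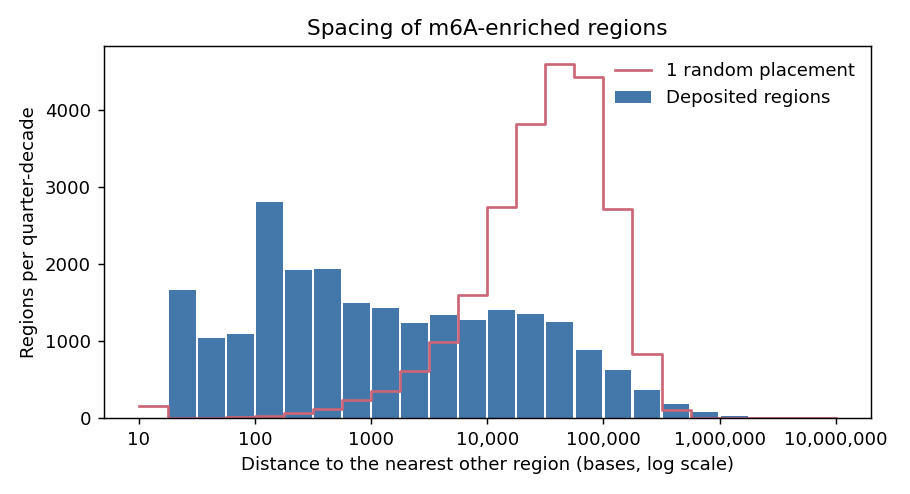
Distance from each enriched region to the nearest other region (x axis, bases, log scale) against the number of regions per quarter-decade (y axis), for the deposited regions (bars) and for 1 random placement of the same widths (line, overlapping placements drawn in the first step). The deposited regions spread from 25 bases upwards with a median of 900 bases, while the random placement lies mostly above 10,000 bases.

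Among 1-Mb bins of the autosomes and X, the one with the most regions was on chromosome 18. This bin, from 37000001 to 38000000, held 173 regions covering 43800 bases, 19.5% of all regions on that chromosome. The median over 2577 bins was 6 regions. The next bins were on chromosome 7 from 134000001 to 135000000 with 79 regions, and on chromosome 10 from 79000001 to 80000000 with 72 regions and from 80000001 to 81000000 with 71. Without the bin from 37 to 38 Mb, the density of chromosome 18 was 8.23 regions per Mb, against 10.1 with it.

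The chromosome 18 bin also held 4 of the 10 loci with the most regions. The largest of these, from 37633401 to 37679900, held 34 regions with 11325 covered bases, the most of any locus. A second one, from 37867901 to 37927675, held 23 regions with 5300 covered bases. Outside chromosome 18, the locus with the most regions lay on chromosome 19 from 9076201 to 9092725, with 22 regions and 6025 covered bases, none of them wider than 500 bases. A locus on chromosome 14, from 61821676 to 61834075, held 17 regions and 7650 covered bases within 12.4 kb. In the 1-Mb bin of chromosome 18 the median region width was 175 bases, against 225 bases over all regions.

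**Figure D4:**
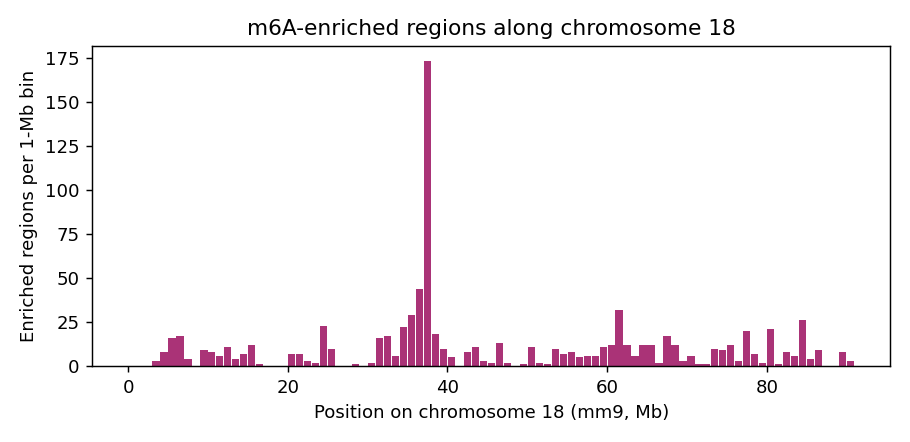
Number of enriched regions (y axis, from 0) in each 1-Mb bin along chromosome 18 (x axis, mm9, Mb). The bin from 37 to 38 Mb holds 173 regions, far above the median bin of the genome, which holds 6.

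The mitochondrial sequence carried 42 peaks in 14 regions. They covered 7200 of the 15375 bases between the first and last peak, or 46.8%. The regions formed 3 blocks. The first ran from base 326 to base 1950 with 3 regions and 89.2% of its bases covered, the second from base 3501 to base 5275 with 6 regions and 85.9% covered, and the last from base 10976 to base 15700 with 5 regions and 89.4% covered. Between the last and the middle block, 5700 bases from 5276 to 10975 held no peak. Of 23402 nuclear windows of the same length, each started at a region, 2 held as many covered bases. These windows overlap one another and can include untranscribed sequence, so their count serves as a scale and not as a test. The highest was on chromosome 14, starting at 61821676, with 7650 covered bases or 49.8%. Mitochondrial DNA is transcribed from both strands into long precursor RNAs, and the list has no strand, so the strand of these regions is open. It also has no heights or input counts, so RNA abundance and enrichment are not separated in this coverage.

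**Figure D5:**
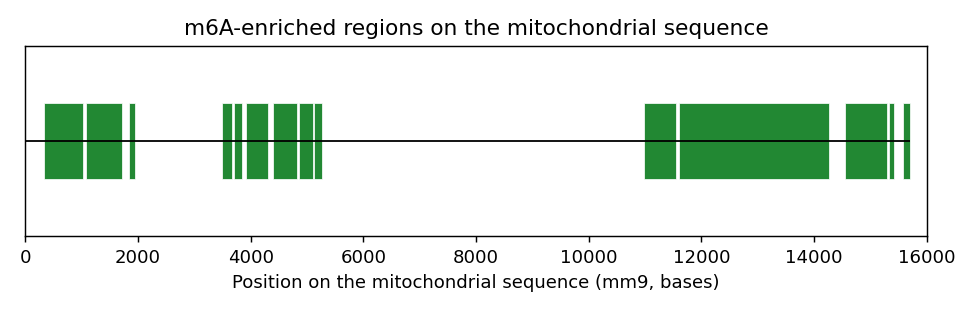
Positions of the 14 enriched regions (green boxes, to scale) along the mitochondrial sequence (x axis, mm9, bases; the vertical direction has no scale). The regions form 3 blocks, and the stretch from 5276 to 10975 has none.

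The sequences labelled random held 46 peaks in 30 regions. The one named for chromosome 9 carried 24 of these peaks in 13 regions covering 4000 bases. The one named for chromosome 1 carried 16 peaks in 13 regions covering 2600 bases.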

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

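No paired analysis was possible because the deposited list holds no value per library; for the same reason no library could be left out, and no stricter cut on peak height could be applied. The settings listed beforehand for transcript region, stop codon distance, motif, gene lists and peaks per gene were not run, since peaks were not placed on genes. Keeping only peaks at or above the median width left 21599 peaks with a median of 175 bases, and joining peaks within 100 bases gave 20988 with a median of 225 bases. Keeping only regions at or above the median width left 11840 regions (median 350 bases) in 7671 loci. It lowered the covered share of the mitochondrial stretch between the first and last peak to 41.6%, by construction, since fewer intervals entered. Joining regions within 100 bases raised that share to 49.3%. The density of X relative to autosomes stayed between 0.418 and 0.488, and that of chromosome 11 between 1.56 and 1.65, when peaks, covered bases, joined regions or only regions at or above the median width were counted. The share of regions with a close neighbour was 38.7% with only the wider regions, 40.4% after joining, 43.6% within 500 bases and 66.9% within 5000 bases. Linking at 5000 and 20000 bases gave 13184 and 9895 loci. Of these alternatives, those of the peak count and the median peak width were fixed before the data were examined, and the rest were added afterwards. Without input counts, expression and enrichment cannot be separated for any of these results.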

Other observations

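The tests of neighbouring widths and of locus edges below had their predictions written before their results were seen, but they and all of their alternatives were chosen after the file had been examined; the mean widths by gap were computed after the results of those tests were seen.

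The genes under the dense bin of chromosome 18 were not determined. The gene table of build GRCm38 lists 57 protein-coding genes named Pcdha, Pcdhb or Pcdhg, the clustered protocadherins, which encode neuronal cell adhesion proteins. All 57 are on chromosome 18, with only 5 other protein-coding genes between the first and the last of them. Whether the 173 regions from 37000001 to 38000000 lie in these genes was not tested, because coordinates of that table do not apply to mm9. These genes share similar sequences, and how reads that fit several copies were counted is not given in the sources used here.

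Regions were unevenly spread at the scale of 1 Mb. Of 2577 bins, 82.3% held at least 1 region, and the densest 10% of bins held 36.4% of all regions.

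Isolated regions, with no other within 10 kb, were slightly narrower than the rest. Their mean width was 277 ± 2.68 bases (SE, n = 6173 regions) against 288 ± 1.68 bases (n = 17273), a difference of -10.7 bases (two-sided permutation p = 0.001). The standard errors and permutations in this paragraph treat each region as independent. Regions near one another are not, so the errors and p-values can be too small. Differences between chromosomes in both measures are argued against, since permuting within chromosomes gave a mean difference of -0.414 bases and left the observed one outside its spread (permutation p = 0.0016). With isolation set at 5000 and at 20000 bases the difference was kept, at -14.0 bases (permutation p = 0.0001, the smallest that 10000 permutations can give) and -10.1 bases (permutation p = 0.0049); after joining regions within 100 bases it was -3.54 bases (permutation p = 0.404), but joining also turns a lone close pair into a wide isolated region by construction. Among regions over 1 kb from any other, isolated regions were 11.4 bases wider (277 against 265 bases, permutation p = 0.0042). The greater width thus lay in regions within 300 bases of another. Means were 311 ± 5.78 bases (SE, n = 1670) at a gap of 25 bases and 319 ± 4.55 bases (n = 2914) at gaps over 25 and up to 100 bases. At gaps over 100 and up to 300 bases the mean was 301 ± 3.53 bases (n = 3971). At gaps over 300 and up to 1000 bases it was 268 ± 3.44 bases (n = 3488), below the 277 bases of isolated regions. Whether the regions within 300 bases of another are long stretches broken by short gaps or separate sites cannot be told apart in a list without heights. The prediction for broken stretches was that, among regions over 1 kb from any other, isolated regions would not be narrower. It was met, which does not exclude separate sites. Broken stretches would make each piece narrower than the whole, but the width of the whole is unknown here. Distances here run along the genome and peaks were not placed on exons, so distances in the spliced RNA are unknown. No biological explanation was tested.

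In many transcripts m6A is known to gather near stop codons and in 3' untranslated regions, which lie toward one end of a gene. The hypothesis that the widest region of a locus lies at its edge was tested in 2857 loci of 3 or more regions. The widest region was outermost in 55.6% of loci against 53.5% in random order, an excess of 2.18 percentage points (one-sided permutation p = 0.013). The excess was 1.25 points with links of 5000 bases, 1.06 with 20000 bases, 1.55 in loci of 4 or more regions and 2.28 after joining within 100 bases; p ranged from 0.013 to 0.391 over the 5 alternatives, and 4 of them did not pass 0.05. After joining regions up to 1000 bases apart, the excess was 0.507 points in 916 loci, so broken stretches cannot be told apart from a real edge preference with so few loci. The hypothesis therefore stays open.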
